A study of Mus musculus with 13 samples.

How the data were processed

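RNA pull-downs with purified dAKAP1 protein were measured by RNA sequencing in 13 libraries: 4 KHT pull-downs, 5 negative control pull-downs (NEG) and 4 libraries of input RNA (IPT), all from MA-10 cells. Per the labels' protocols, the cells were grown in RPMI medium with horse serum, RNA was extracted with Trizol before and after the pull-down, and libraries were made with a stranded total RNA kit with depletion of ribosomal RNA. The input's description also names depletion of ribosomal RNA, while the labels' molecule field names polyA RNA, and which of these holds was not settled. Samples were grouped by title, because the description field of the KHT samples speaks of negative control experiments while their treatment field and titles name KHT. The labels do not say which NEG library came from empty beads, MBP or KHT(GDDG), so NEG was 1 group.

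The deposited table holds estimated counts per gene (expected counts, unscaled) for all 13 libraries; per the submitters' processing notes, kallisto and DESeq2 were used with the builds GRCm38 and mm10, with no versions and no roles given. How transcript estimates became gene values is not given in the sources used here, nor is any filter on genes. The values were already whole numbers, so rounding changed none. Values of 2 outnumbered values of 1 in each of the 12 libraries with counts, as values that count both mates of a pair would give, which was not settled. Also, 1 pair of 7SL RNA genes had identical values, so reads of near-identical copies were shared. Rnu1a1 and several gene models likewise had the same fold change and p in limma voom for KHT with IPT. All sample columns but NEG 2, which was 0 throughout, entered the tests, so 12 libraries were fitted where all 13 had been planned. Symbols for 27004 of 27071 identifiers came from a gene name table, and coordinates from an annotation of the same build, GRCm38. Transcript length and GC content were not in the references used here.

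Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; glmQLFit with robust estimation, glmQLFTest) in 1 fit of the 3 groups, with TMM scaling and filterByExpr, which kept 10714 genes. Tests were two-sided and adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05 on the adjusted p. The comparisons were KHT with NEG, KHT with IPT and NEG with IPT, and genes higher in KHT than in both were the intersection of the calls. That intersection was set beside independent lists of the same sizes and beside 20 draws in which all libraries, KHT included, were simulated without group differences. Library measures were compared by two-sided exact permutation tests. These fits, the 23 gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

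Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) for the 21 lists with at least 3 tested members, and with an estimated correlation and fry as alternatives. The lists covered mitochondria (nuclear oxidative phosphorylation, mitochondrially encoded messenger RNAs, mitochondrial ribosome, import, citric acid cycle with pyruvate metabolism, fatty acid oxidation, carriers, dynamics and outer membrane, tRNA synthetases), the reported dAKAP1 ligands and kinase A anchoring and signalling. They also covered the cytosolic ribosome, translation factors, secretory pathway, glycolysis, steroidogenesis, cholesterol synthesis, replication-dependent histones, nuclear RNAs with snoRNA hosts, Zfp genes, and markers of Sertoli cells, germ cells, and macrophages, endothelium and peritubular cells. The ligands were taken from background knowledge. Members were counted at an adjusted p over all genes and, beside it, adjusted over the list alone.

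The rule for named genes took the 12 largest and 8 smallest changes between KHT and NEG, the 10 largest and 6 smallest between KHT and IPT, and the 6 largest and 6 smallest between NEG and IPT. It held for genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, and it skipped unnamed models and pseudogenes. Up to 4 members of each list with the smallest p were added, of which the text names some, and always Akap1, Sod2, Atp5j2, Star, Larp4, Actb and Gapdh.

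Features with at least 0.5% of pooled NEG counts were called dominant, which gave 9. A gene at 0 in all libraries of a group was compared with a floor of 3 counts over that group, and a group with 1 to 3 counts was given as a ratio with its exact binomial counting interval. Floors and counting intervals cover counting error only, and both are too narrow if the values count both mates of a pair. NEG libraries held 31318 to 49062 counts outside the dominant features, against at least 929348 in each KHT and IPT library.

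The fit was tested on counts simulated from these libraries with 100 genes changed 2-fold and 100 changed 4-fold among 10714. It called 3% and 27% of them for KHT with NEG, 11% and 83% for KHT with IPT, and 0% and 30% for NEG with IPT, with 1, 5 and 3 unchanged genes called. In each of the 3, camera called the 1 list that had been raised and 0 of 20 others. The simulated genes were drawn independently, so this does not show how the preset correlation fares on lists of correlated genes. For KHT with NEG the estimated correlation was 0.27 for the citric acid cycle list and 0.21 for the histones. Alternatives were DESeq2 size factors, total counts alone, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma voom with sample weights, the 2 groups compared alone, the replicate number as a block, a test against a 2-fold change and each library left out in turn. Further alternatives were chosen after seeing the data: counts outside the dominant features as library size, TMM with singleton pairing, halved values, and NEG 5 as the sole NEG library. NEG 5 alone carries the replicate number 5, so the replicate block fits it by itself and is not separate from leaving it out. A surrogate variable came from sva 3.50.0. DESeq2 gave no adjusted p for 1484, 30 and 1277 genes in the 3 comparisons, which were counted as not called.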

Results

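The series measured which RNAs were held by the RNA-binding part of dAKAP1, a protein that anchors protein kinase A and other signalling enzymes at the outer mitochondrial membrane. Purified protein of its KH and Tudor domains, called KHT here, carried a maltose-binding protein (MBP) tag. It was mixed with total RNA of MA-10 cells, a mouse Leydig tumour line that makes steroids, and was pulled down with an antibody against the tag. The 13 libraries were 4 KHT pull-downs, 5 negative control pull-downs (NEG) and 4 libraries of the RNA that went in (IPT). The NEG libraries came from empty beads, MBP alone or a KHT protein named with GDDG, and which library was which is not given in the sources used here. NEG 2 held 0 counts, which left 12 libraries and 4 per group. Total estimated counts were 1618998, 1162178, 1503489 and 1218366 in NEG 1, 3, 4 and 5. They ran from 1955446 to 3689792 in KHT and from 2487679 to 3085423 in IPT. Between 2173 and 7047 features had at least 1 count in a NEG library, 16194 to 18532 in a KHT library and 17246 to 18903 in an IPT library.

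The NEG libraries were made almost wholly of 9 features, led by CT010467.1 (45.3% of pooled NEG counts) and Lars2 (34.2%), loci at which reads of ribosomal RNA are known to collect. These 9 features took 97.1% ± 0.964 of NEG counts, 42.9% ± 9.88 of KHT counts and 32.6% ± 5.62 of IPT counts (SD, n = 4 each). NEG differed from KHT and from IPT with p = 0.0286 each in two-sided exact permutation tests over 70 assignments, the smallest p that 4 against 4 libraries can give. The adjusted p was 0.0735 over the 18 tests of library measures. KHT and IPT differed with p = 0.114 in the exact permutation test (adjusted p = 0.171). Outside the 9 features, NEG libraries held 31318 to 49062 counts, KHT libraries 929348 to 2101632 and IPT libraries 1542713 to 2237374. Messenger RNAs of the mitochondrial genome made up 1.86% ± 0.120 of these remaining counts in KHT and 1.65% ± 0.152 in IPT (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.114). Named pseudogenes made up 4.56% ± 2.52 of the remaining counts in NEG and 0.414% ± 0.0846 in IPT (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0735). By library, named pseudogenes held 6.55%, 5.16% and 5.66% in NEG 1, 3 and 4 but 0.876% in NEG 5, below KHT 2 (1.03%). None of the 18 adjusted values was under 0.05. The p-values here and below measure the spread between these libraries alone, since nothing in the labels says that they came from separate cultures.

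**Figure D1:**
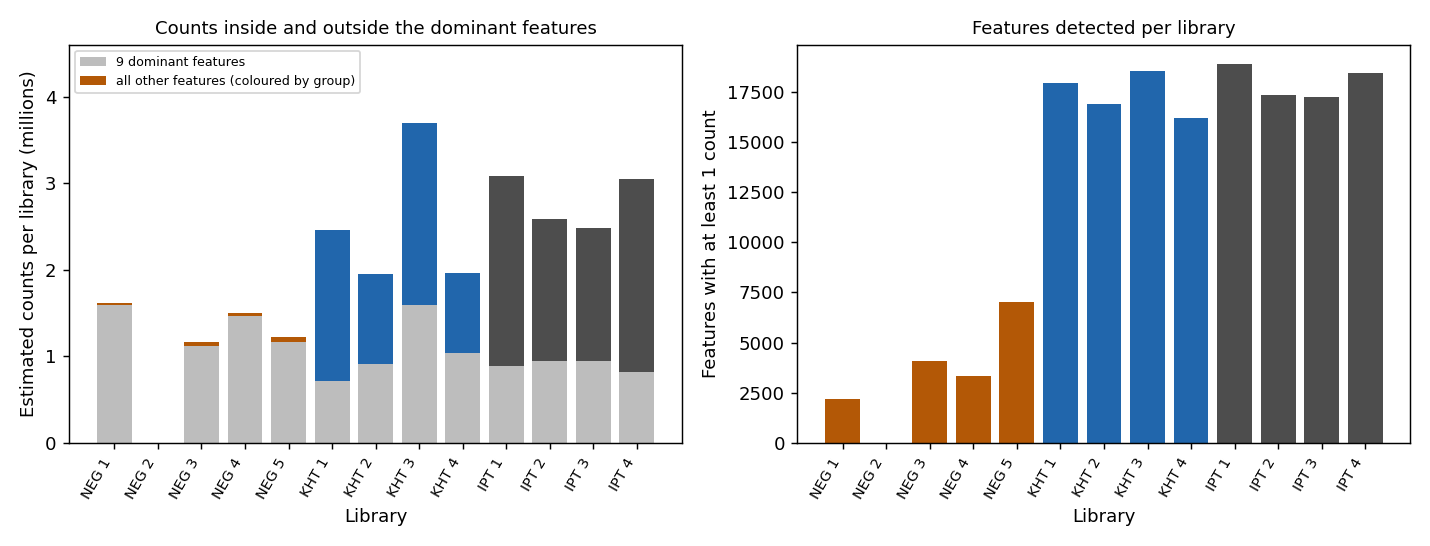
Estimated counts per library, inside the 9 dominant features (grey) and outside them (coloured by group), and the number of features with at least 1 count per library. NEG 2 held 0 counts, the other NEG libraries held 31318 to 49062 counts outside the 9 features, and each KHT and IPT library held at least 929348.

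The comparison of KHT with NEG asks which RNAs the bait held above the background of the pull-down. Rpl13, a protein of the large ribosomal subunit, stood at 120 ± 26.2 normalised counts-per-million (CPM; SD, n = 4) in KHT and at 0 in each NEG library. It was at least 32.8-fold higher in KHT against a floor of 3 counts over the NEG group (edgeR adjusted p = 0.000586; chromosome 8, 123102350 to 123105244, GRCm38). The mitochondrially encoded complex I subunit mt-Nd3 (112 ± 57.6 CPM, at least 33.4-fold) and the ribosomal protein gene Rpl9 (69.0 ± 8.44 CPM, at least 17.8-fold) were likewise at 0 in NEG. So were the histone H4 genes Hist1h4n (at least 18.1-fold) and Hist1h4k (at least 16.0-fold). The same held for Nme2, a nucleoside diphosphate kinase (at least 15.3-fold), Nup188 of the nuclear pore (at least 12.2-fold) and Capza1, which caps actin filaments (at least 10.96-fold). Htt, the huntingtin gene, was at least 9.57-fold higher and Tbc1d8 at least 9.26-fold higher. Hist1h2ap (at least 10.6-fold) and Rpl17 (at least 10.8-fold; KHT 35.3 ± 27.6 CPM) completed the 12 genes with the largest change. All 12 were above 0 in the 4 KHT libraries, with edgeR adjusted p-values between 0.000586 and 0.0057. Scaled by total counts alone, the bounds were larger, such as 561-fold for Rpl13 and 304-fold for Rpl9. Histone and ribosomal protein genes have near-identical copies, so the share of reads given to each is uncertain.

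Star, which moves cholesterol into mitochondria at the start of steroid synthesis, stood at 43.8 ± 18.2 CPM in KHT and 7.21 ± 14.4 in NEG (SD, n = 4 each; log2 fold change 2.35, SE 0.79, edgeR adjusted p = 0.0293; chromosome 8, 25808474 to 25815982). Its 7 NEG counts lay in NEG 5 alone. The edgeR call of Star ended without NEG 1 (adjusted p = 0.100), NEG 3 (0.0818), NEG 4 (0.0780), KHT 3 (0.0598) or KHT 4 (0.0505). It also ended with a mean of at least 10 CPM (0.0558), with the counts outside the 9 features as library size (0.0556), with halved values (0.0590) and against a 2-fold change (0.0772). Larp4, an RNA-binding protein known as a partner of dAKAP1, stood at 105 ± 6.98 CPM in KHT and 23.4 ± 17.0 in NEG (SD, n = 4 each; log2 fold change 2.21, SE 0.70, edgeR adjusted p = 0.0228). Larp4 lost the call in the fit of the 2 groups alone (0.109), with a mean of at least 10 CPM (0.0619) and against a 2-fold change (0.0694). Sod2, the mitochondrial superoxide dismutase, was at 23.2 ± 6.15 against 8.61 ± 6.12 CPM (1.39, SE 0.58, edgeR adjusted p = 0.0675). Atp5j2, a subunit of ATP synthase, was at 27.0 ± 5.35 against 7.21 ± 14.4 CPM (1.64, SE 0.70, edgeR adjusted p = 0.0700). Star, Sod2 and Atp5j2 are the reported dAKAP1 ligands, a list taken from background knowledge of earlier work. Of these 3, 1 passed over all genes and 3 when adjusted over the list alone (median log2 fold change 1.64). Without NEG 5, Sod2 (0.0375) and Atp5j2 (0.000689) also passed over all genes, as they did in DESeq2 (0.0351 and 0.0146). Atp5j2 also passed without the filter (0.0358), in limma voom (0.00110) and with the replicate block (0.00415). The block fits NEG 5, the sole library with that number, by itself, so it is not separate from leaving NEG 5 out. Akap1, the gene of the bait protein, was at 39.7 ± 7.23 against 26.1 ± 29.4 CPM (0.72, SE 0.60, edgeR adjusted p = 0.320). Actb, the beta-actin gene (1.63, adjusted p = 0.129), and Gapdh, a glycolytic enzyme (1.12, adjusted p = 0.332), did not pass in edgeR, and both did without NEG 5 (0.00393 and 0.0175), in limma voom (0.00504 and 0.00594) and with the replicate block (0.00746 and 0.0201). Under total counts Sod2 (5.40), Atp5j2 (5.60), Akap1 (4.85), Actb (5.42) and Gapdh (4.87) all passed as higher in KHT, beside a median over all genes of 5.67.

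Over all 10714 genes tested, 3324 were higher and 291 lower in KHT than in NEG, with a median log2 fold change of 1.73. The list counts and medians below stand beside these values. The 1.73 includes fitted values of genes at 0 in NEG, which are no measure of size. It was 1.16 in the fit of genes with a mean of at least 10 CPM. A list median under 1.73 therefore does not show that the list rose less than other genes. Among mitochondrial groups, 12 of 18 measured genes of the citric acid cycle and pyruvate metabolism were higher in KHT than in NEG and none was lower, 14 when adjusted over the list alone. Their median log2 fold change was 2.06, or 1.98 with genes at 0 in NEG set at their bound. No median with such bounds was taken over all genes, so list medians with bounds have no like value beside them. Pcx, pyruvate carboxylase, rose from 4.61 ± 5.91 CPM in NEG to 42.4 ± 5.99 in KHT (SD, n = 4 each; 3.07, edgeR adjusted p = 0.00474). Dlst of the oxoglutarate dehydrogenase complex had 929 counts in KHT and 3 in NEG, all in NEG 5 (ratio 9.90, 95% counting interval 3.38 to 48.1; edgeR adjusted p = 0.00494). Such floors and intervals are too narrow if the values count both mates of a read pair, which was not settled. The list passed camera (adjusted p = 0.00117), and its adjusted p was 0.813 with an estimated correlation. Of 78 nuclear genes of oxidative phosphorylation, 19 were higher and 6 lower, the same counts as when adjusted over the list alone (median 1.06, with bounds 1.03). Cyc1, cytochrome c1, rose (3.07, edgeR adjusted p = 0.0062). Ndufab1, the mitochondrial acyl carrier protein, stood at 185 ± 108 CPM in NEG and 19.96 ± 12.4 in KHT (log2 fold change -3.20, edgeR adjusted p = 0.00272) but was higher in KHT under total counts (0.97). Of 13 mitochondrially encoded messenger RNAs 2 were higher, mt-Nd3 and mt-Nd4l (at least 8.18-fold), also 2 when adjusted over the list alone (median 1.06). Of 77 mitochondrial ribosome genes 21 were higher and 1 lower (20 and 1 adjusted over the list alone; median 1.46, with bounds 1.06). Mrpl18 was at least 4.59-fold higher and Mrpl21 was lower (-1.97, edgeR adjusted p = 0.00448), though higher under total counts (2.12).

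Genes of mitochondrial import were higher in KHT than in NEG in 11 of 33 and lower in 1, alike when adjusted over the list alone (median 1.39, with bounds 1.16). Samm50 of the outer membrane sorting complex had 613 counts in KHT and 2 in NEG (ratio 9.80, 95% counting interval 2.70 to 81.1; edgeR adjusted p = 0.00691), and Timm8a1 was at least 2.73-fold higher. Solute carriers of the inner membrane were higher in 18 of 36 and lower in 1 (20 and 1 adjusted over the list alone; median 2.42, with bounds 1.29), including Slc25a23 (at least 3.37-fold). Fatty acid oxidation genes were higher in 6 of 17, also 6 adjusted over the list alone (median 1.34, with bounds 1.34). Hadhb of the trifunctional protein had 712 counts in KHT and 2 in NEG (ratio 11.4, 95% counting interval 3.14 to 94.2; edgeR adjusted p = 0.00473). Dynamics and outer membrane genes were higher in 8 of 23 and lower in 1, alike over the list alone (median 1.40, with bounds 1.28). Rhot1, which links mitochondria to motors, had 646 counts in KHT and 3 in NEG (ratio 6.89, 95% counting interval 2.35 to 33.5; edgeR adjusted p = 0.0128). The porin gene Vdac2 was lower (-1.43, edgeR adjusted p = 0.0176) but higher in KHT under total counts (2.72), and lost the call without NEG 4 (0.0578) or KHT 1 (0.0519), without the filter on low counts (0.177), in the 2 groups alone (0.142) and against a 2-fold change (0.138). Mitochondrial tRNA synthetases were higher in 9 of 17 and lower in 1, Lars2, alike over the list alone (median 2.598, with bounds 0.67). Vars2 was at least 3.21-fold higher.

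Outside mitochondria, 33 of 60 replication-dependent histone genes were higher in KHT than in NEG and none was lower, 38 when adjusted over the list alone (median 2.32, with bounds 1.64). This list passed camera (adjusted p = 6.6e-08), with an adjusted p of 0.813 with an estimated correlation. Of 78 cytosolic ribosomal protein genes 27 were higher and 10 lower (29 and 10 over the list alone; median 1.38, with bounds 1.37). Of 59 translation factor genes 12 were higher and 5 lower (11 and 5 over the list alone; median 0.98, with bounds 0.91). The former included Eif2s1 of the initiator tRNA-binding complex (2.78, edgeR adjusted p = 0.00516). The latter included Eif3m (-2.45, edgeR adjusted p = 0.00391) and Eif3f (-2.51, adjusted p = 0.0042), both of initiation factor eIF3 and both higher in KHT under total counts (1.70 and 1.73). Genes of the secretory pathway were higher in 7 of 31 and lower in 3, alike over the list alone (median 1.15, with bounds 1.04). Stt3a of the oligosaccharyltransferase was higher (1.79, edgeR adjusted p = 0.0125), with the call lost in the fit of the 2 groups alone (0.122) and against a 2-fold change (0.0773). Its partner Ost4 (-2.70, edgeR adjusted p = 0.00895) and the signal peptidase gene Sec11c (-2.55, adjusted p = 0.00445) were lower, though higher under total counts (1.52 and 1.59). Kinase A anchoring and signalling genes were higher in 7 of 25, also over the list alone (median 1.65, with bounds 1.42), among them Akap13, an anchoring protein (2.74, edgeR adjusted p = 0.0079).

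Steroidogenic and Leydig cell genes were higher in KHT than in NEG in 7 of 21, also when adjusted over the list alone (median 1.43, with bounds 1.43). Tspo of the outer mitochondrial membrane had 756 counts in KHT and 2 in NEG (ratio 12.1, 95% counting interval 3.34 to 100.005; edgeR adjusted p = 0.00564). Fdxr, which passes electrons to steroidogenic enzymes, also rose (3.07, edgeR adjusted p = 0.00637). Cholesterol synthesis genes were higher in 6 of 22 (5 over the list alone; median 1.58, with bounds 1.58), among them Sqle, squalene epoxidase (3.01, edgeR adjusted p = 0.0107). Glycolytic genes were higher in 2 of 15, also over the list alone (median 1.40, with bounds 1.37). These were the kinases Hk2 (2.81, edgeR adjusted p = 0.00508) and Pfkl (2.30, adjusted p = 0.0173, with the call lost without NEG 1 at 0.0540, with halved values at 0.0648 and against a 2-fold change at 0.0627). Nuclear RNAs and snoRNA host genes were higher in 6 of 21, also over the list alone (median 1.59, with bounds 1.20). Neat1, the RNA of paraspeckles, was among them (2.99, edgeR adjusted p = 0.0231), with the call lost without NEG 3 (0.0600) or NEG 4 (0.0550), in the 2 groups alone (0.0650) and against a 2-fold change (0.0562). Zinc finger genes named Zfp were higher in 64 of 252 (54 over the list alone; median 2.33, with bounds 0.52), including Zfp654 (at least 5.49-fold). None of the 4 Sertoli cell markers passed (median 3.42, with bounds -0.10). Ddx4 was the single germ cell marker tested of 3 in the file. It passed over the list alone, which for 1 gene is no adjustment, with KHT counts too few to clear the floor. Of the 2 endothelial markers Pecam1 was lower in KHT (-4.09, edgeR adjusted p = 6.0e-05) but level under total counts (0.02), and Cdh5 did not pass (0.47, adjusted p = 0.630). Of the 21 lists tested, those of the citric acid cycle and of the histones alone passed camera. Without NEG 5, camera also called the mitochondrially encoded messenger RNAs (adjusted p = 0.000626), fatty acid oxidation (0.00420), glycolysis (6.6e-05), steroidogenesis (0.00982) and cholesterol synthesis (0.000915), all upwards. With the replicate block, which fits NEG 5 by itself much as leaving it out does, camera called the same 5 upwards and translation factors downwards. Without NEG 3 it called fatty acid oxidation (0.0477) and glycolysis (0.0284). All these calls used the preset correlation. In the fit of all libraries, camera with an estimated correlation gave an adjusted p of 0.813 for each of these lists. For 7 lists with positive medians camera, which sets a list against all other genes, gave the direction down, none of them passing.

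Under the rule for named genes, which skips unnamed models and pseudogenes, genes lower in KHT than in NEG were led by Rps13, a protein of the small ribosomal subunit. It stood at 4.07 ± 3.20 CPM in KHT and 601 ± 424 in NEG (SD, n = 4 each, log2 fold change -7.17, SE 1.10, edgeR adjusted p = 0.000691). Map7d2, a microtubule-binding protein, stood at 1.19 ± 0.598 against 60.3 ± 26.2 CPM (-5.63, SE 0.52, edgeR adjusted p = 1.9e-06). The microRNA locus Mir6240 stood at 4.92 ± 2.88 against 194 ± 84.2 CPM (-5.32, edgeR adjusted p = 9.1e-06). These 3 were also lower under total counts (-2.86, -1.52 and -1.25). The microRNA locus Mir6236 (-5.51), Lars2 (-5.37), the scaffold protein gene Grip2 (-5.05), C2cd4c (-5.00) and the P-cadherin gene Cdh3 (-4.70) passed under TMM. They did not pass under total counts, where the values were -1.42, -1.28, -1.09, -1.04 and -0.70. Mir6236 and Lars2 are among the 9 dominant features. In each group Grip2 had most counts in the library where the dominant feature Gm19220 had most. These were NEG 3 (2591 and 36798), KHT 2 (2218 and 48553) and IPT 3 (4730 and 82744). C2cd4c and Cdh3 also had their highest IPT values in IPT 3. What links these features was not tested. Without the filter on low counts, Mir6236 (edgeR adjusted p = 0.100) and Lars2 (0.262) also lost the call. With NEG 5 as the sole control, Rps13 (edgeR adjusted p = 0.404), Grip2 (0.0669), C2cd4c (0.111) and Cdh3 (0.103) did.

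Over all 10714 genes tested, edgeR's quasi-likelihood test called 3324 higher and 291 lower in KHT than in NEG (5233 at an unadjusted p under 0.05). Of the tested genes 2986 (27.9%) had 0 counts in all NEG libraries. The median gene lay at 1.73 on the log2 scale with TMM scaling, at 1.43 with the counts outside the 9 features as library size and at 5.67 under total counts, so single changes are relative to that shift. Under total counts 10428 genes were higher and 14 lower, and 141 of the 291 genes lower under TMM were called higher. The count of higher genes moved to 1721 without NEG 1 and to 5421 without NEG 5, and that of lower genes to 174 without NEG 3, 186 without NEG 4 and 454 without NEG 5. With NEG 5 as the sole control, an alternative chosen after the data were seen, edgeR called 184 higher and 37 lower, with the spread taken from KHT and IPT and the lone NEG library assumed to vary like them. Of 86 single genes called and followed through the alternatives, 20 then kept their edgeR call, 64 lost it and 2 reversed. Among the 12 genes with the largest change, mt-Nd3 (0.118) and Rpl17 (0.394) lost it. So did Star (0.735), Pcx (0.135), Dlst (0.179), Cyc1 (0.200), Hadhb (0.206), Rhot1 (0.4495), Tspo (0.290), Fdxr (0.214), Akap13 (0.191), Eif2s1 (0.118), Mrpl18 (0.0906), Vdac2 (0.801) and Stt3a (0.183).

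The comparison of KHT with IPT asks which RNAs were enriched over their abundance in the RNA that went in. The reported ligands lay near the input level. Star differed by -0.01 on the log2 scale (95% interval -1.05 to 1.04), Sod2 by -0.05 (-0.70 to 0.60) and Atp5j2 by -0.22 (-1.04 to 0.59), with 4 libraries per group and an edgeR adjusted p of 1.00 each. Akap1 differed by 0.06 (-0.88 to 1.00), Larp4 by -0.00 (-1.23 to 1.22), Actb by -0.28 (-1.99 to 1.44) and Gapdh by -0.27 (-2.15 to 1.61), with the same adjusted p. The pseudogene Rpl38-ps2 was the only gene of 10714 that passed edgeR, and it was higher in KHT (log2 fold change 7.05, 95% interval 4.90 to 9.20, adjusted p = 0.0412). It had 75, 19, 23 and 53 counts in the 4 KHT libraries and 1, 0, 0 and 0 in IPT (ratio 224, 95% counting interval 39.6 to 8894), and 10 counts in NEG 5. It was named after its values were seen. Its edgeR call ended without NEG 4 (adjusted p = 0.219) or any of the 4 IPT libraries (0.347 to 0.682), under DESeq2 size factors (0.0702), under total counts (0.0714), against a 2-fold change (0.0827) and with counts outside the 9 features as library size (0.0579). With a mean of at least 10 CPM or halved values it was not tested, being filtered out. The number of genes called higher was 0 in all of these, except without IPT 1, where another gene model passed.

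In none of the 23 lists did a member differ between KHT and IPT, over all genes or adjusted over the list alone. Nuclear oxidative phosphorylation genes lay below the input as a list (0 of 78 passed, median -0.11, camera adjusted p = 0.0396). The adjusted p was 0.967 with an estimated correlation and 0.106 under total counts. Camera's adjusted p was 0.228 without KHT 1, 0.447 without KHT 2, 0.171 without IPT 2, 0.116 without IPT 3 and 0.492 without IPT 4. The member with the smallest p, Ndufc2 of complex I, stood at 7.98 ± 1.78 CPM in KHT and 14.1 ± 3.96 in IPT (SD, n = 4 each; -0.81, edgeR adjusted p = 1.00). The mitochondrially encoded messenger RNAs had the highest median of the lists (0.13), with 12 of 13 above 0. Among them mt-Co2, a subunit of cytochrome oxidase, stood at 78.5 ± 53.9 against 31.96 ± 27.2 CPM (1.29, edgeR adjusted p = 1.00) and mt-Co3 at 358 ± 45.4 against 228 ± 72.7 (0.65, adjusted p = 1.00). In the fit of all libraries no list but that of nuclear oxidative phosphorylation passed camera. With 1 surrogate variable in the fit of KHT and IPT, that list did not pass (0.255), and the mitochondrially encoded messenger RNAs did, upwards (camera adjusted p = 0.00634, and an adjusted p of 0.927 with an estimated correlation). Camera also called cholesterol synthesis downwards without KHT 3 (adjusted p = 0.0237), KHT 4 (0.0455) or IPT 1 (0.0127), at the preset correlation. In the fit of all libraries, camera with an estimated correlation gave this list an adjusted p of 0.967. Medians lay at -0.21 for glycolysis, -0.15 for fatty acid oxidation and for cholesterol synthesis, -0.11 for steroidogenesis, -0.05 for the ligands and -0.04 for import and for the citric acid cycle. They lay at -0.00 for kinase A genes and for carriers at 0.00, 0.01 for the mitochondrial ribosome, 0.02 for dynamics and for tRNA synthetases, and 0.05 for the cytosolic ribosome. Translation factors, the secretory pathway and nuclear RNAs stood at 0.01, histones at 0.00, zinc finger genes at 0.08 and Sertoli markers at -0.01. The germ cell marker (0.01) and the 2 endothelial markers (0.10) were too few for a list test. Median and mean differed in sign for the mitochondrial ribosome (mean -0.02), the histones (mean -0.01) and the Sertoli markers (mean 0.01), and camera's direction went against the median for these and for the carriers and the citric acid cycle.

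Of the 10714 genes, 175 had an unadjusted p under 0.05 between KHT and IPT, where chance alone gives 535.7. Counts of higher and lower genes were 1 and 0 in edgeR, 4 and 3 in DESeq2, and 2 and 10 in limma voom. Among the latter was Rnu1a1, the RNA of the U1 splicing particle (edgeR -2.11, adjusted p = 0.348, and limma voom -2.09, adjusted p = 0.00177), which has near-identical copies. The gene models Gm26444, Gm23804, Gm22068, Gm22317, Gm22634 and Gm25679 had the same value and adjusted p in limma voom. The 10 lower genes there thus do not stand for 10 separate RNAs. The 95% interval of the difference lay within 2-fold for 53.7% of genes in the fit of all libraries. In the fit of KHT and IPT alone it did so for 68.6% of genes, and for 90.4% of the 281 genes of the nuclear mitochondrial lists. The count of higher genes was 2 without KHT 4, and that of lower genes was 2 without KHT 1 and 1 without KHT 2. Without the filter on low counts 43 genes were higher and 13 lower.

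RNAs held by the bait above both background and input would be higher in KHT than in NEG and than in IPT. No gene met both in edgeR, and none did under any alternative run, DESeq2 and limma voom included. Rpl38-ps2, the single gene above input, differed from NEG by -0.85 on the log2 scale (edgeR adjusted p = 0.435). Under total counts it was higher in KHT than in NEG (3.11, edgeR adjusted p = 0.00242) and did not pass against IPT (6.98, adjusted p = 0.0714). Independent lists of the sizes found would share 0.31 genes, and unchanged groups simulated against the same KHT libraries shared a mean of 0.05 over 20 draws (1 at most). Those draws called at most 1 gene against NEG and 5 against IPT, so a near-empty overlap was given beforehand and says nothing on the real one.

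**Figure D2:**
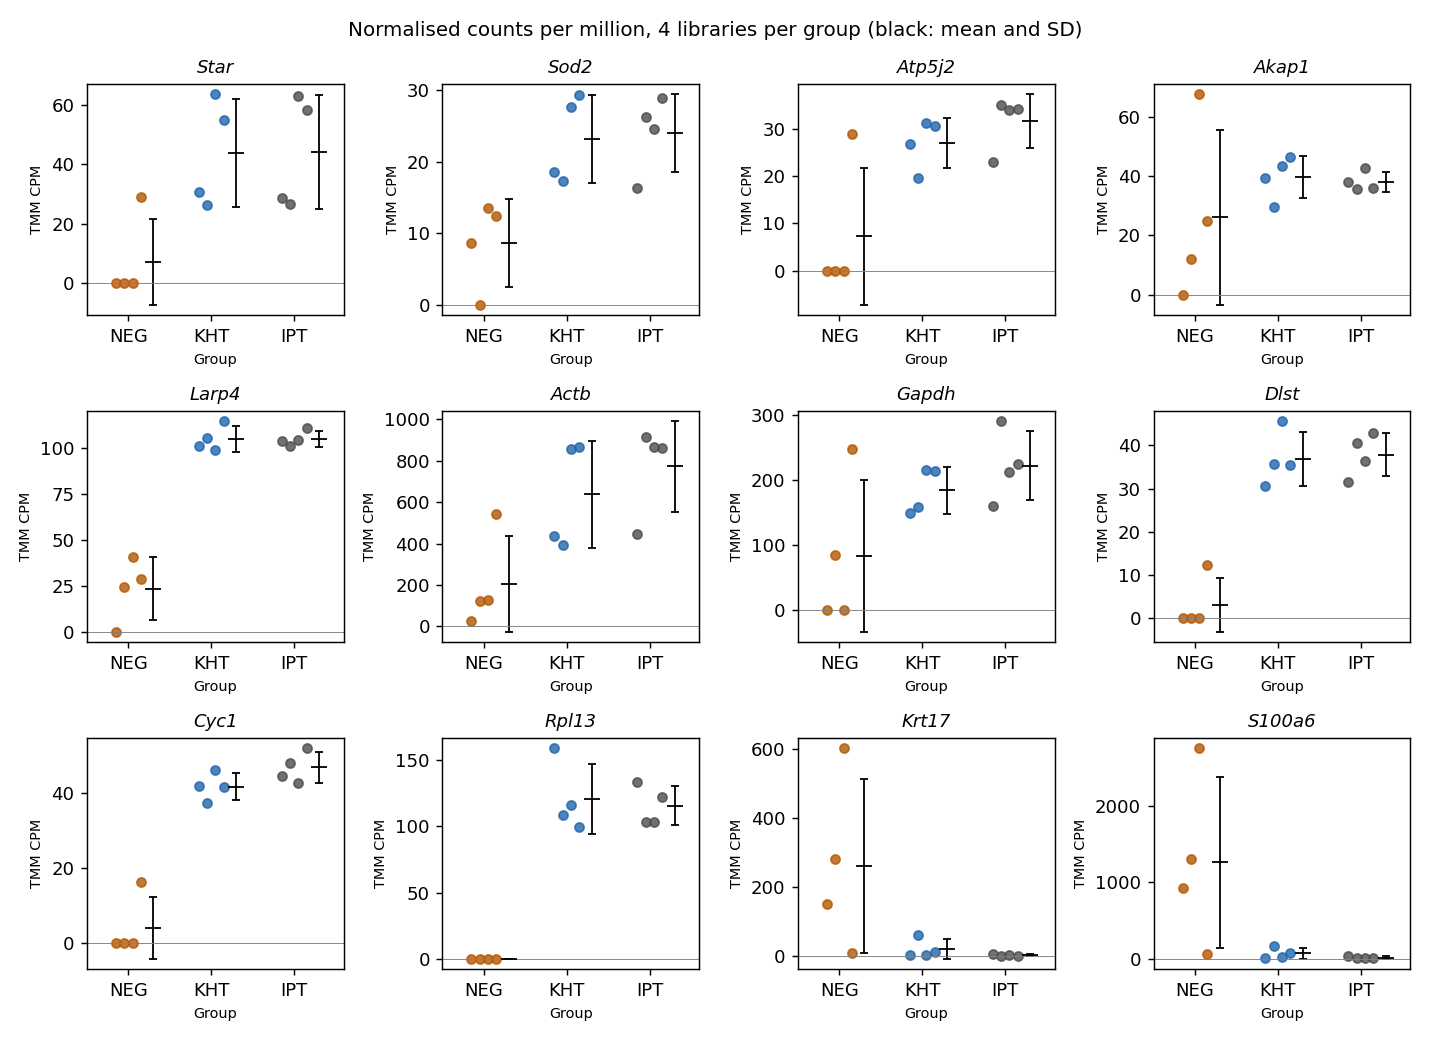
Normalised counts-per-million (TMM) of 12 genes in the 4 NEG, 4 KHT and 4 IPT libraries with counts, each point a library, with the mean and SD of each group in black. Star, Sod2, Atp5j2 and Larp4 lie at like levels in KHT and IPT, Rpl13 is at 0 in NEG, and Krt17 and S100a6 have their highest means in NEG under TMM (under total counts Krt17 differs by 0.42 on the log2 scale in favour of KHT, and by -0.02 for S100a6, neither passing).

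The comparison of NEG with IPT describes the background of the pull-down itself. Krt17, a keratin of stratified epithelium, stood at 260 ± 253 CPM in NEG and 1.41 ± 2.37 in IPT (SD, n = 4 each; log2 fold change 7.44, edgeR adjusted p = 0.0194; chromosome 11, 100256215 to 100261029). S100a6, a calcium-binding protein, stood at 1261 ± 1120 against 13.5 ± 13.6 CPM (6.54, SE 1.34, edgeR adjusted p = 0.00325). Both missed the edgeR threshold under total counts (2.78, adjusted p = 0.115, and 1.90, adjusted p = 0.0842). The olfactory receptor gene Olfr907 stood at 476 ± 313 against 4.72 ± 3.64 CPM (6.64, edgeR adjusted p = 0.00134). Sfrp1, a secreted inhibitor of Wnt signalling (6.60, edgeR adjusted p = 0.00443), and Map7d2 (6.15, adjusted p = 4.3e-07) were also higher in NEG. These 3 were higher under total counts too (2.13, 2.24 and 1.77). Mir6236, a dominant feature, passed (6.11, edgeR adjusted p = 3.0e-05), but not under total counts (1.70, adjusted p = 0.0927) or without the filter on low counts (0.0661). Pecam1, an endothelial adhesion molecule, stood at 113 ± 61.9 against 3.62 ± 0.319 CPM (4.92, edgeR adjusted p = 3.9e-06), without a call under total counts (0.50). Genes at 0 in all NEG libraries were led by Rpl13 (115 ± 14.6 CPM in IPT, at least 30.8-fold lower in NEG), mt-Nd3 (at least 25.2-fold), Rpl9 (at least 21.3-fold), Hist1h4n (at least 16.8-fold), Hist1h4k (at least 15.7-fold) and Rpl17 (at least 15.4-fold).

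Star (-2.36, edgeR adjusted p = 0.0277), Larp4 (-2.22, adjusted p = 0.0218) and Atp5j2 (-1.87, adjusted p = 0.0410) were lower in NEG than in IPT. Sod2 (-1.44, edgeR adjusted p = 0.0560), Akap1 (-0.66, adjusted p = 0.359), Actb (-1.91, adjusted p = 0.0830) and Gapdh (-1.39, adjusted p = 0.228) did not pass. The Star call ended without NEG 1 (0.0946), NEG 3 (0.0768), NEG 4 (0.0727), IPT 3 (0.0581) or IPT 4 (0.0548). It also ended with a mean of at least 10 CPM (0.0512), with counts outside the 9 features as library size (0.0509), with halved values (0.0549) and against a 2-fold change (0.0728). The Atp5j2 call ended without NEG 1 (0.131), NEG 3 (0.104), NEG 4 (0.0998), IPT 2 (0.0668), IPT 3 (0.0640) or IPT 4 (0.0654). It ended too with a mean of at least 10 CPM (0.0847), in the 2 groups alone (0.0625), with counts outside the 9 features as library size (0.0789), with halved values (0.0670) and against a 2-fold change (0.117). The Larp4 call ended in the 2 groups alone (0.0828), with a mean of at least 10 CPM (0.0582) and against a 2-fold change (0.0656). Sod2 passed without NEG 5 (0.0318) or IPT 1 (0.0458), under DESeq2 size factors (0.0443), without the filter (0.0423), in DESeq2 (0.0250) and with the replicate block (0.0449). Actb and Gapdh passed without NEG 5 (0.00232 and 0.0109), in limma voom (0.000898 and 0.00278) and with the replicate block (0.00532 and 0.0152), and Actb also in DESeq2 (0.0206). The replicate block again fits NEG 5 by itself and is not separate from leaving it out. Sod2, Akap1, Actb and Gapdh all passed as lower in NEG under total counts. Over all 10714 genes tested, 390 were higher and 3482 lower in NEG than in IPT (median -1.74), beside which the lists below stand. The -1.74 was likewise taken without bounds.

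Replication-dependent histones were lower in NEG than in IPT in 35 of 60 (40 adjusted over the list alone; median -2.38, with bounds -1.77; camera adjusted p = 1.4e-07, and 0.869 with an estimated correlation). Citric acid cycle genes were lower in 12 of 18 (14 over the list alone; median -2.11, with bounds -2.02; camera adjusted p = 0.00194, and 0.869 with an estimated correlation), among them Dlst. Fatty acid oxidation genes were lower in 5 of 17 (9 over the list alone; median -1.47, with bounds -1.45) and glycolytic genes in 3 of 15 (2 over the list alone; median -1.55, with bounds -1.54), both with a camera adjusted p of 0.0186, and of 0.869 with an estimated correlation. Cholesterol synthesis genes were lower in 6 of 22 (6 over the list alone; median -1.75, with bounds -1.75; camera adjusted p = 0.0277, and 0.869 with an estimated correlation). The calls of fatty acid oxidation (0.0594 and 0.0586), glycolysis (0.0620 and 0.0586) and cholesterol synthesis (0.0899 and 0.101) ended without IPT 2 or IPT 4. That of cholesterol synthesis also ended without IPT 3 (0.157) and under total counts (0.477), and that of glycolysis under total counts (0.7104). Camera gained the list of nuclear oxidative phosphorylation downwards under total counts (adjusted p = 0.0490). It gained mitochondrially encoded messenger RNAs and steroidogenesis downwards without NEG 5 (0.00307 and 0.00836) and with the replicate block (0.0160 and 0.0138), where translation factors were called upwards (0.0385). These gains used the preset correlation. In the fit of all libraries, camera with an estimated correlation gave an adjusted p of 0.977 for nuclear oxidative phosphorylation and 0.869 for each of the other lists gained.

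Among lists that did not pass camera between NEG and IPT in the fit of all libraries, 25 of 78 nuclear oxidative phosphorylation genes were lower and 6 higher (alike over the list alone; median -1.21, with bounds -1.14), the higher ones including Ndufab1 (4.11, edgeR adjusted p = 0.000551; -0.36 under total counts, not passing). Mitochondrially encoded messenger RNAs were lower in 2 of 13, also over the list alone (-0.96). Mitochondrial ribosome genes were lower in 24 of 77 and higher in 2, alike over the list alone (-1.36, with bounds -1.16), and import genes lower in 10 of 33 and higher in 1 (8 and 1 over the list alone; -1.54, with bounds -1.20). Carriers were lower in 17 of 36 and higher in 1 (18 and 1 over the list alone; -2.38, with bounds -1.30). Dynamics genes were lower in 7 of 23 and higher in 1, alike over the list alone (-1.46, with bounds -1.42). Mitochondrial tRNA synthetases were lower in 8 of 17 and higher in 1 (10 and 1 over the list alone; -2.51, with bounds -0.81), and the ligands lower in 2 of 3 (3 over the list alone; -1.87). Kinase A genes were lower in 8 of 25 and higher in 1 (10 and 1 over the list alone; -1.72, with bounds -1.26). Cytosolic ribosome genes were lower in 26 of 78 and higher in 12 (30 and 13 over the list alone; -1.32, with bounds -1.23), translation factors lower in 14 of 59 and higher in 5 (10 and 5 over the list alone; -1.01, with bounds -0.85). Secretory genes were lower in 8 of 31 and higher in 3 (9 and 3 over the list alone; -1.17, with bounds -1.11), steroidogenic genes lower in 7 of 21 and higher in 1 (10 and 1 over the list alone; -1.63, with bounds -1.63). Nuclear RNAs were lower in 5 of 21, also over the list alone (-1.46, with bounds -1.10), and zinc finger genes in 64 of 252 (50 over the list alone; -2.20, with bounds -0.40). The 4 Sertoli markers did not pass (-3.48, with bounds 0.12), and Pecam1 was the 1 higher of 2 endothelial markers. Ddx4 passed over the list alone, again without any adjustment.

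Over all genes edgeR called 390 higher and 3482 lower in NEG than in IPT (median -1.74; 5330 at an unadjusted p under 0.05). Under total counts the numbers were 50 and 10423 (median -5.92), and 159 of the 390 genes higher under TMM were called lower. Without NEG 1 the count of lower genes was 1792 and without NEG 5 it was 5447, and with NEG 5 as the sole control edgeR called 45 higher and 192 lower, its spread again taken from KHT and IPT. Of 82 single genes called and followed through the alternatives, 13 then kept their edgeR call, 67 lost it and 2 reversed. Krt17 (0.832), S100a6 (0.670), Olfr907 (0.688), Sfrp1 (0.443), Star (0.7325) and Atp5j2 (0.864) did not pass edgeR then.

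**Figure D3:**
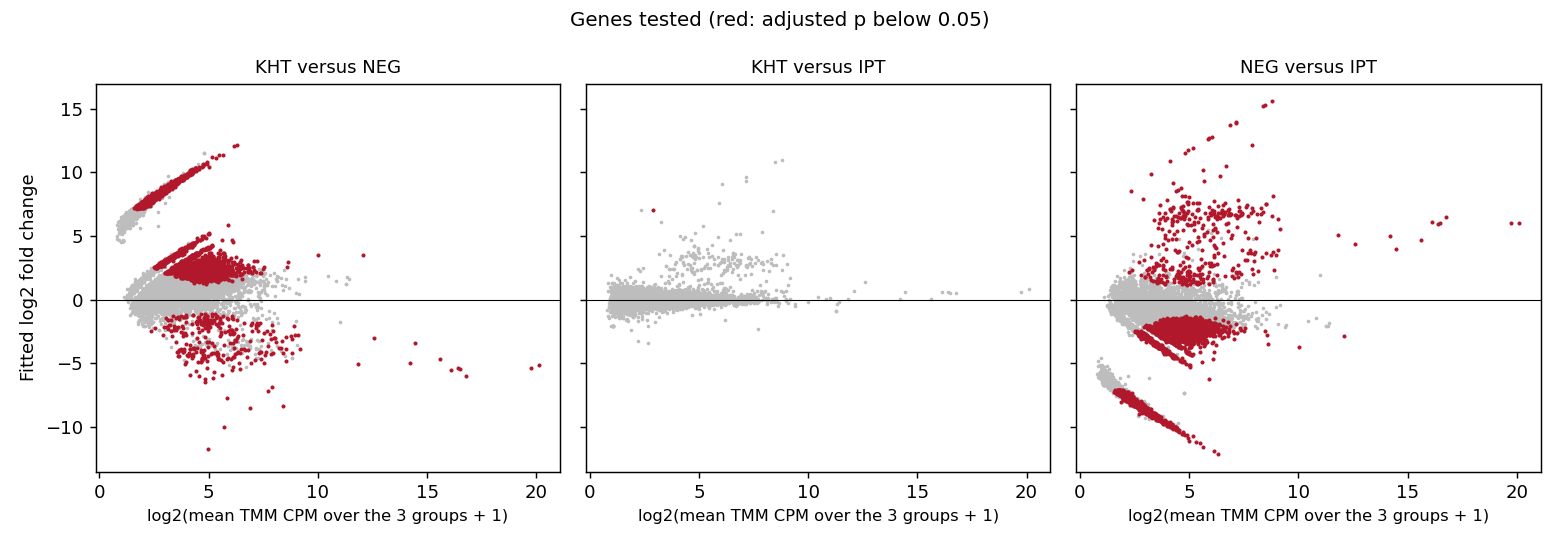
Fitted log2 fold change against the log2 of the mean TMM CPM plus 1 over the 3 groups for the 10714 genes tested in each comparison, with genes at an edgeR adjusted p under 0.05 in red. KHT versus NEG has 3324 red points above 0 and 291 below, KHT versus IPT 1 above 0, and NEG versus IPT 390 above and 3482 below (under total counts 10428 and 14, 0 and 0, and 50 and 10423), and the outer bands are genes at 0 or near it in NEG, whose fitted values are no measure of size.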

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

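Of the tests below, those of the spread of the NEG libraries, of depth between KHT and IPT, of scaling, of carry-over and of reads shared with pseudogenes were chosen after the result was seen, and so were the 91 genes examined for libraries that stand apart. The tests of library structure, of epithelial genes, of olfactory receptors and of other splits were chosen before, and that of thinned depth before its own result but after that of the test it replaced.

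In normalised CPM, 44 of 273 groups of 4 libraries had a highest or lowest library far from the rest, and none of 18 groups of library measures did. Chance gives about 1 in 20 groups, which is no measure for these genes: some had been picked because a library stood apart, and in 18 of the 44 groups a single library held all counts. NEG 5 was the highest NEG library, at 41.21 for Rpl38-ps2, 28.85 for each of Star, Atp5j2 and Sqle, 16.49 for Cyc1 and for Fdxr, 12.36 for Dlst, Ndufc2 and Rhot1, 8.243 for Tspo, Hadhb, Zfp451 and Pdhb, 4.121 for Slc25a36 and 177.2 for Nr4a1. It was the lowest for Pecam1 (20.61). NEG 3 was the highest NEG library for C2cd4c (645.1), Asns (36.51), Aldh1l2 (24.34), Samm50 (12.17) and Chac1 (6.085). IPT 1 was the highest IPT library for Trib3 (78.03), Aldh1l2 (76.64), Ddit3 (64.6), Asns (45.14), Tbc1d8 (40.95), Rhot1 (32.89), Chac1 (19.24), Krt17 (4.944), Ddx4 (3.762) and Rpl38-ps2 (0.1075), and the lowest for Actb (448.3) and Atp5j2 (23). IPT 3 was the highest for Grip2 (710.8), C2cd4c (30.96) and Cdh3 (11.42) and the lowest for Ndufab1 (8.416), and IPT 4 was the highest for Eif2s1 (43.68). KHT 2 was the highest KHT library for Nme2 (92.35), Ost4 (54.12) and Rnu1a1 (0.9212) and the lowest for Hist1h2ap (29.48). KHT 3 was the highest for mt-Rnr1 (5595) and Cdh5 (18.01).

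The first pattern is that few genes differed between KHT and IPT, 1 in edgeR (175 at an unadjusted p under 0.05), 7 in DESeq2 and 12 in limma voom. Several of those in limma voom had the same values and are not separate. A spread set by the NEG libraries is argued against by the fit of KHT and IPT alone, which called 2 genes. A lack of depth could hide changes beyond 2-fold. For 68.592% of genes the 95% interval lay within 2-fold in that fit (53.7% in the fit of all libraries), which gene by gene leaves no room for such a change. These genes were picked by the same intervals, which were not adjusted for the number of genes, so the share is no separate test of depth. A lack of depth stays open for the other 31.408%, whose intervals reached past 2-fold. In the fit of all libraries a simulated 2-fold change was called in 11% of genes, while the fit of KHT and IPT alone was not simulated. These parts were divided after the value was seen. Library structure that crosses the groups was fitted as 1 surrogate variable, which set KHT 1, KHT 2 and IPT 1 apart from the rest. That fit called 4 genes (Gm37357 -1.49, Gm10800 -2.78, Rpl38-ps2 7.28 and Gm25939 -2.21), although such a fit leans towards more calls. It had 453 genes at an unadjusted p under 0.05, against 312 without the variable and 545.4 by chance. Fitting the structure thus did not bring out many calls. With fewer small p-values than chance gives, this fit cannot exclude that the structure hides differences. For the genes with narrow intervals, RNA held by the bait may thus mirror the input within 2-fold, a hypothesis found and examined in the same libraries, and binding that differs between RNAs below 2-fold stays open and untested.

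The second pattern is the 291 genes lower in KHT than in NEG. A few features taking most of the NEG counts cannot be told apart: 4.811% of the genes (14) were also lower under total counts, but the TMM factors shift every gene by 4.10 on the log2 scale, which by itself leaves 93 genes below 0 where 88 were found, a condition added after the values were seen. After thinning of each KHT and IPT library to 1162178 counts, 83.85% of them (244) were still lower, which argues against total depth as the whole cause. This test replaced one of detected features after thinning (15392 in the poorest KHT library against 7047 in the richest NEG library, a ratio of 2.184), whose result had been seen, because it did not measure the lower genes. The low number of NEG counts outside the 9 features was not thinned to, and no biological explanation was tested.

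The third pattern is that pseudogenes and Krt17, S100a6, Sfrp1 and Cdh3 stood higher in NEG, under TMM or outside the 9 features. Under total counts KHT differed from NEG by 0.42 for Krt17, -0.02 for S100a6, 0.20 for Sfrp1 and -0.70 for Cdh3, none passing edgeR. Against IPT, Sfrp1 was then higher in NEG (2.24) and Cdh3 did not pass (0.30, edgeR adjusted p = 0.586). For these genes the pattern against KHT thus depends on the scaling. For pseudogenes, Krt17 and S100a6 the higher level came chiefly from NEG 1, 3 and 4. In counts-per-million outside the 9 features, Krt17 stood at 1118, 1170 and 2570 there, 40.8 in NEG 5 and 251 in KHT 2. S100a6 stood at 6865, 5471 and 11752 in the former, 326 in NEG 5 and 685 in KHT 2. With counts outside the 9 features as library size, 374 genes were higher in NEG than in both KHT and IPT. Carry-over of KHT or IPT RNA alone would not give that. These genes were picked by that same difference, however, so the count is no separate test of carry-over. For NEG counts as a whole carry-over cannot be told apart. Their median correlation with input was 0.5105 of that of thinned input (0.279 to 0.846 by library). The parts were divided after these values were seen. Reads shared between ribosomal protein genes and their pseudogenes, if split alike in all libraries, would give like shares on pseudogenes. The shares were 52.0%, 45.9% and 42.5% in NEG 1, 3 and 4, against at most 21.5% in KHT (KHT 2) and 11.5% in IPT. These values argue against such an even split for NEG 1, 3 and 4. A split that differs by gene stays open there, as 31, 46 and 52 of 78 ribosomal protein genes were detected, against 78 in each KHT and IPT library. For NEG 5 (20.7%) the explanation stays open, at 1.802 times the highest IPT share but below KHT 2. The comparison with KHT was added after these values were seen. RNA of stratified epithelium is a candidate source that stays open. The 20 listed genes were chosen without Krt17 and Cdh3 because these had been seen. Of them 16 were in the file, 14 with counts in IPT and 8 with counts in NEG. By an exact binomial test on pooled counts, which covers counting error only, 6 were higher in NEG than in IPT. They were led by Krt14 (369 against 1.71 counts-per-million outside the 9 features) and Krt10 (104 against 1.71), while Dsc3 was lower (25.9 against 84.1). Perp and Col17a1, also among the 6, had 2 NEG counts each. Of the 6, all but Dsp (2.58 against 6.57) also stood higher in KHT than in IPT, with Krt14 at 22.5 and Krt10 at 6.70 in KHT. This difference of KHT from IPT was not tested. Genomic DNA stays open too, with olfactory receptors other than Olfr907 at 1.446 times the IPT share (NEG 924 to 1565, IPT 823 to 940), a value under the bound set beforehand by less than the NEG spread, a condition applied after the value was seen, and no biological explanation was tested.

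Each comparison was set beside the 35 splits of its 8 libraries into groups of 4. Between KHT and NEG 1 split, the real one, gave as many genes (3615, highest other 271), the smallest share that 35 splits can give. All other splits put NEG libraries, with few counts outside the 9 features, together with KHT libraries. That widens the spread within groups, so few calls were to be had there and chance is not excluded by this test. As many gene lists came from 8 splits (2, highest other 7), so for lists chance cannot be excluded either. Between KHT and IPT 10 gave as many genes (1, highest other 143) and 20 as many lists (1, highest other 3), so chance cannot be excluded. The split with 143 genes put KHT 1, 2 and 4 with IPT 1, which points to a structure of the samples. Between NEG and IPT 1 split, the real one, gave as many genes (3872, highest other 245), again the smallest share possible and with the same limit. As many lists came from 2 splits (5, highest other 9), so for lists chance cannot be excluded.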

How the results depend on the processing

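Counts outside the 9 features as library size, TMM with singleton pairing, halved values and NEG 5 as the sole control were chosen after seeing the data, and all other alternatives before. In the order KHT higher than NEG, KHT lower than NEG, KHT higher and lower than IPT, and NEG higher and lower than IPT, the numbers of genes were 3324, 291, 1, 0, 390 and 3482. Where they moved by more than 1.5 times, they were 10428, 14, 0, 50 and 10423 under total counts (KHT higher than IPT the third), which differ from TMM by construction in the 9 features. Without the filter they were 791 lower than NEG, 43 and 13 for KHT with IPT, and 987 higher in NEG than in IPT. With a mean of at least 10 CPM they were 1173 higher than NEG, 0 higher than IPT and 1236 lower in NEG than in IPT, where fewer genes were tested. DESeq2 gave 4 and 3 and limma voom 2 and 10 for KHT with IPT, and DESeq2 size factors gave 0 higher there. The 2 groups alone gave 2103 higher than NEG, 1 lower than IPT and 2046 lower in NEG than in IPT. Against a 2-fold change they were 1734, 150, 0 and 1771 (higher and lower than NEG, higher than IPT, NEG lower than IPT), a stricter test by construction. Outside the 9 features as library size, 0 were higher than IPT. Halved values gave 1762 higher than NEG, 0 and 1 for KHT with IPT, and 1901 lower in NEG than in IPT. NEG 5 as the sole control gave 184 and 37 for KHT with NEG (162 and 15 of them the same genes), 1 lower than IPT, and 45 and 192 for NEG with IPT, with fewer samples by construction and the spread taken from KHT and IPT alone. For the others the cause was not tested. TMM with singleton pairing moved no count by more than 1.5 times.

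With each library left out in turn, the lowest and highest numbers were 1721 and 5421 higher and 174 and 454 lower for KHT with NEG, 0 and 2 higher and 0 and 2 lower for KHT with IPT, and 310 and 512 higher and 1792 and 5447 lower for NEG with IPT. Genes higher in KHT than in both NEG and IPT stayed at 0 under every alternative run. On values centred by group, the replicate numbers did not pair the libraries. Over 5379 genes, correlations of same-numbered libraries were 0.107, -0.537, 0.227 and 0.144 between KHT and IPT. They were -0.117, -0.141 and 0.089 between KHT and NEG and 0.110, -0.027 and -0.004 between NEG and IPT, and KHT 2 went best with IPT 1 (0.661). Uncentred Spearman correlations between KHT and IPT were highest for KHT 1 with IPT 1 (0.9577) and KHT 3 with IPT 3 (0.9564), and lowest for KHT 2 with IPT 2 (0.8288). Pairing thus stays open for some libraries. With the replicate block 5042 genes were higher in KHT than in NEG, and 8 gene lists were called between KHT and NEG and 8 between NEG and IPT.

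Gene lists called numbered 2 for KHT with NEG, 1 for KHT with IPT and 5 for NEG with IPT. They were 0, 0 and 0 with an estimated correlation, 20, 0 and 20 with fry, which asks whether a list moves by itself, and 0 for KHT with IPT under total counts. With each library left out they ran from 2 to 7 for KHT with NEG (4 without NEG 3, 7 without NEG 5), from 0 to 2 for KHT with IPT (2 without KHT 3, KHT 4 or IPT 1) and from 2 to 7 for NEG with IPT (2 without IPT 2 or IPT 4, 7 without NEG 5).

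Among single genes, 18 values reversed, the cause of which was not tested beyond the scaling itself. Under total counts the difference of KHT from NEG turned positive for Ndufab1 (0.97), Mrpl21 (2.12), Vdac2 (2.72), Eif3m (1.70), Eif3f (1.73), Sec11c (1.59), Ost4 (1.52) and Pecam1 (0.0175, adjusted p = 0.969, the others passing), and that of NEG from IPT negative for Ndufab1 (-0.36), Mrpl21 (-1.96), Eif3m (-1.61), Eif3f (-1.87), Sec11c (-1.25) and Ost4 (-1.05), of which Ndufab1 (0.445) and Ost4 (0.0670) did not pass. With NEG 5 as the sole control the signs reversed for Eif3f (1.16 and -1.07) and Ost4 (1.63 and -0.88), none passing (adjusted p = 0.502 and 0.554, and 0.613 and 0.7695). Of the other single-gene values 3489 kept direction and side of the threshold, 241 lost their call, 131 of these with NEG 5 as the sole control, 89 gained one and 44, without a call before or after, moved by more than their standard error (16 with NEG 5 as the sole control), while 24 values of single lists lost their call. Besides the libraries named with the results, Rhot1 lost its call between NEG and IPT without NEG 1 (0.0522). A correction for transcript length and GC content was not run, since the references held neither. NEG libraries held 31318 to 49062 counts outside the 9 features. A simulated 4-fold change was called in 27% of genes for KHT with NEG, with all groups drawn from 1 pooled profile. Depth was not separated there from the spread between NEG libraries.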

Other observations

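Some genes, picked after their values were seen, differed between libraries of the same group. Trib3, a pseudokinase of the response to amino acid shortage, stood at 379, 302 and 331 counts-per-million outside the 9 dominant features in KHT 1, KHT 2 and IPT 1, and at 25.2, 22.6, 6.74, 24.6 and 8.94 in KHT 3, KHT 4, IPT 2, IPT 3 and IPT 4. Aldh1l2 of mitochondrial folate metabolism stood at 373, 321 and 325 in the former libraries and at 4.29 to 15.1 in the latter. Ddit3, a transcription factor of the stress response, stood at 255, 227 and 274 against 35.5 to 57.0, and Asns, asparagine synthetase, at 216, 177 and 191 against 28.2 to 78.6. Chac1, which breaks down glutathione, stood at 78.2, 86.7 and 81.6 against 3.58 to 12.9. Ppp1r15a, which restores translation after stress, stood at 231, 200 and 229 against 23.7 to 48.1.

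Other genes picked in the same way went the opposite way in the same libraries. The early response gene Nr4a1 stood at 39.1, 28.6 and 40.6 in KHT 1, KHT 2 and IPT 1 against 271 to 1056 in the other 5, and Cyp11a1, which starts steroid synthesis from cholesterol, at 114, 119 and 109 against 379 to 579. Thbs1, a secreted matrix protein, stood at 0, 2.86 and 0.912 against 72.3 to 107. The surrogate variable of KHT and IPT was 0.427, 0.519 and 0.418 in KHT 1, KHT 2 and IPT 1 and between -0.293 and -0.255 in the others. These libraries are not a group of the study, and no test of these differences was run.

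The gene model Gm3379 stood at 607, 305, 722 and 204 counts-per-million outside the 9 features in the 4 NEG libraries with counts and at 0 in each KHT and IPT library. In KHT 3, CT010467.1 took 30.2% of all counts and AY036118 had 0, where each other library with any counts had at least 15273. Spearman correlations over genes, which are not independent replicates, ran from 0.8288 to 0.958 between KHT and IPT libraries from 0.202 to 0.470 between NEG libraries and from 0.1393 to 0.6432 between NEG and the others. NEG 5 stood at 0.5875 to 0.6432 with the KHT and IPT libraries and at 0.202 to 0.327 with the other NEG libraries.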
